A study of Mus musculus with 48 samples.

How the data were processed

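Sequencing of 3′ ends measured polyadenylated RNA in 3 tables of mouse cells: 32 libraries of moDC and pDC treated with TLR ligands, 6 libraries of moDC and pDC after knockdown or overexpression, and populations sorted from bone marrow and spleen, of which 9 were used. The stimulation table holds whole counts of reads per gene symbol as deposited by the authors, with column totals that differ between libraries. The other 2 tables hold estimated counts per gene symbol as deposited by the authors, of which 10.2% (perturbation) and 15.8% (sorted populations) are not whole, and these were rounded to whole counts first. TopHat and the genome build mm9 are named in the submitters' processing notes. The counting tool, its handling of reads with several hits and any filter are not given in the sources used here, and no coordinates are printed. The stimulation table has 21637 genes, of which 19411 symbols matched the reference gene table used for names. Reads that match closely related genes, such as the Ear, Lyz and Klk1b families, could be split between them by the counting, so values of such genes are uncertain. In each of the 3 tables, a row without a gene name was left out of library sizes and tests, and held 0.187% to 0.938% of the counts of a stimulation library. Columns were matched to samples by name. The hairpin columns of GM-CSF cells are headed cDC in the table and moDC in the sample titles, and the titles were followed. Among the sorted populations 1 column could not be matched by name to the CD4+ DC sample or any other and was not used.

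In the stimulation libraries 1 count was worth 1.34 to 3.92 counts-per-million units (CPM), and a count of 0 allows a level of up to 4.01 to 11.8 CPM (3 counts of the total). In the perturbation libraries 1 count was worth 3.81 to 25.4 CPM, and in the sorted populations 0.194 to 1.14 CPM. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. No test compared values across the 3 tables.

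Each condition in the stimulation experiment is 1 library, so the tests take the spread from the model's residuals. Log2 fold changes came from edgeR's quasi-likelihood fit (edgeR 4.0.16 in R 4.3.3) with TMM scaling, on genes with at least 20 CPM in at least 4 libraries of the fit. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and a fold of at least 2, and the test is two-sided. The cell type comparison used all 32 libraries with the condition (ligand and time) as a block. Late responses compared the 4 and 6 h libraries of a ligand with the untreated library of the cell type, in 1 fit of all 32 libraries with no block. There the 4 and 6 h libraries of a ligand formed 1 group, so their differences count as spread. The time comparison set 4 and 6 h against 1 h within each cell type with the ligand as a block. The interaction of cell type and time used both cell types. LPS was compared with PAM, and CpG A with CpG B, with the time as a block, and the difference of these contrasts between cell types was tested in a joint fit. Standard errors were taken from the log2 fold change and its F statistic. The late responses of a cell type share 1 untreated library, so no overlap between them was computed.

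The gene lists were fixed before the data were examined: pDC identity, monocyte and macrophage, conventional DC, type I and III interferon, interferon-stimulated, inflammatory cytokine and NF-kB, immediate early, DC maturation, TLR sensing, MHC class II presentation, cell cycle, C/EBP family, IRF family, neutrophil and granule, B cell, T cell, NK cell, erythroid, basophil with mast cell and eosinophil, stem and progenitor, and reference genes. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. List counts are over all genes unless given as adjusted over the list alone. Genes named in the text follow a rule set at the same time. It takes the 10 largest changes per direction among calls with the same sign in every pair (5 against the untreated library), Cebpb and Irf8, up to 4 members of each list with the largest change, and the member that goes most against its list. For single libraries it takes the targeted gene, Cebpb, Irf8, the 10 largest ratios per direction among genes reaching 100 CPM and up to 4 members of each list. For sorted populations it takes the 5 genes per population farthest above every other population. Members of the pDC identity list and of the MHC class II list that are given by population were chosen after their values were seen. The text names a part of the genes that the rule takes.

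Perturbation libraries were compared as log2 ratios of CPM with 10 CPM added, with exact binomial 95% intervals of the ratio of counts. The median ratio of a list was placed among 10000 random lists of the same size matched on mean expression. Lists of 100 moDC genes and 100 pDC genes with the largest folds in the stimulation experiment, and the same sign in all 16 pairs, were added to the fixed ones, and 82 of the pDC genes are in the perturbation table. Correlations of Cebpb and Irf8 used log2(CPM + 5) with exact permutations for 9 populations and 100000 resamples for 16 libraries, adjusted over 3 relations. These ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

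Each fit was tested on simulated counts with 1 real mean per gene over all its libraries and the real library sizes, in which 100 genes changed 3-fold and 100 genes 8-fold. The simulated libraries had no other differences between ligands, times or cultures. The recovery and false calls below therefore hold under the model's own assumptions and may not hold for the real libraries. The cell type fit (8056 genes) recovered 100% of both. The late responses against untreated (8056 genes) recovered 22% (LPS), 28% (PAM), 26% (CpG A) and 29% (CpG B) of the 3-fold changes in moDC and 27%, 23%, 31% and 23% in pDC, and of the 8-fold changes 76%, 76%, 76% and 68% in moDC and 77%, 63%, 71% and 81% in pDC. The time comparisons recovered 97% and 100% in moDC (6426 genes) and 94% and 100% in pDC (7009 genes) at 3-fold and 8-fold, and the late interaction 63% and 93% (7781 genes). LPS against PAM recovered 87% and 100% in moDC (5676 genes) and 85% and 100% in pDC (6404 genes), and CpG A against CpG B 88% and 99% in moDC (5564 genes) and 76% and 96% in pDC (5642 genes). The differences of these contrasts recovered 47% and 85% (7289 genes) and 25% and 83% (6876 genes). Of unchanged genes at most 0.257% were called, in pDC with CpG A against CpG B. Random lists shifted by 1 on the log2 scale had a median percentile of 100, and unshifted ones of 36.4 (20 lists each).

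The alternatives were DESeq2's size factors, DESeq2 1.42.0 as the test, no filter, a filter of 100 CPM, the 1 and 2 h libraries in place of the late ones, no block for condition or time, and leaving out each condition, ligand or time in turn. For single libraries and correlations they were added values of 1 and 20 CPM, median ratio scaling, other minimum levels, and fewer libraries. Scaling by column totals alone, fits without the CpG A libraries, the other pDC control library, and the moDC gene list without granulocyte genes were added after the data were seen. Pseudocount and variance trend alternatives planned for normalised values were not run, as the values are counts. Data of the CD4+ DC population and the reads themselves were not used here.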

Results

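RNA was sequenced from the 3′ ends of transcripts in mouse dendritic cells (DC), cells that sense microbes and start immune responses. Bone marrow cells grown with GM-CSF are called moDC (monocyte-derived DC) in the labels, and those grown with Flt3L are called pDC (plasmacytoid DC, known for making type I interferon). In a stimulation experiment of 32 libraries, 16 per cell type, cells were left untreated or given a Toll-like receptor (TLR) ligand. The ligands were lipopolysaccharide (LPS, sensed by TLR4), the compound that the labels call PAM, and the DNA oligonucleotides CpG A and CpG B, sensed by TLR9. LPS, PAM and CpG B were sampled at 1, 2, 4 and 6 h and CpG A at 1, 4 and 6 h. A perturbation experiment of 6 libraries covered moDC with a control hairpin or a hairpin against Cebpb, pDC with a control hairpin or a hairpin against Irf8, and pDC with a control or a Cebpb overexpression vector. Cebpb encodes a C/EBP transcription factor of myeloid cells, and Irf8 encodes an interferon regulatory factor needed for the development of several DC types. A last table gave 9 cell populations sorted from mouse bone marrow or spleen, named here as in the labels. Total counts per library were 255062 to 748152 in the stimulation experiment (median 397712), 39447 to 262557 in the perturbation experiment and 873734 to 5148680 in the sorted populations. No condition had a replicate library, so p-values in the stimulation experiment measure the spread between single libraries of different conditions, and the lone untreated library of each cell type is assumed to vary like the others.

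The first question was which genes separate moDC from pDC, over the 16 conditions sampled in both. The genes known to mark each cell type were far apart. Ly6d, a surface protein of pDC and lymphoid precursors, had a log2 fold change (moDC over pDC, ± standard error) of -7.11 ± 0.17, at 9.13 against 1290 counts-per-million units (CPM). Siglech, a pDC lectin, had -6.73 ± 0.21 (2.46 against 274 CPM), and Bcl11a, a transcription factor of the pDC lineage, had -5.46 ± 0.33. In the other direction stood the chitinase-like gene Chi3l3 (listed as CHI3L3; 6.16 ± 0.16, 981 against 13.3 CPM), the lectin Clec4n (4.69 ± 0.13, 3180 against 131 CPM) and the Fc receptor Fcgr3 (4.04 ± 0.14). Cebpb was higher in moDC (3.27 ± 0.12, 586 against 59.8 CPM) and Irf8 was lower (-2.01 ± 0.22, 318 against 1180 CPM, adjusted p = 1.14e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

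Of the pDC identity list, 16 of 19 tested members were lower in moDC, and of the monocyte and macrophage list 19 of 23 were higher, while Ms4a7 alone was lower (-2.98 ± 0.19). Conventional DC genes went both ways, with 7 of 21 higher and 11 lower. The chemokine Ccl17 (6.60 ± 0.20, 11100 against 139 CPM) and the transcription factor Irf4 (2.34 ± 0.13) were higher, and the growth factor receptor Flt3 (-5.35 ± 0.24) and Cd8a (-5.29 ± 0.35) lower. Of 27 inflammatory genes 17 were higher in moDC and 3 lower (camera adjusted p = 0.255 with an estimated correlation). Il1a was at 5.41 ± 0.23, whereas Il10, an anti-inflammatory cytokine, had -2.38 ± 0.45. Of 12 genes of MHC class II presentation 6 were lower and 1 higher (camera adjusted p = 0.197 with an estimated correlation), with H2-Ab1 at -1.92 ± 0.092 and 1490 against 5700 CPM. The TLR list split, with 4 of 16 higher, including Tlr4 (2.95 ± 0.20), and 6 lower, including the CpG receptor Tlr9 (-2.97 ± 0.14). The counts of the remaining lists were DC maturation 6 of 15 higher and 3 lower (camera adjusted p = 0.416 with an estimated correlation), immediate early genes 2 of 19 higher and 8 lower, interferon-stimulated genes 2 of 30 higher and 4 lower, cell cycle 3 of 21 lower (0.197), C/EBP family 3 of 6 higher, IRF family 1 of 8 higher and 2 lower, and type I and III interferon 0 of the 1 gene that passed the filter. None of the 5 tested reference genes was called.

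Genes of other blood cells differed as well. The granule proteins of neutrophils were higher in moDC for 11 of 12 tested genes, with S100a8 at 4.48 ± 0.11 (3320 against 150 CPM) and the collagenase Mmp8 at 5.13 ± 0.15. All 6 tested genes of the basophil, mast cell and eosinophil list were higher, led by the eosinophil proteins Epx (6.79 ± 0.15, 577 against 4.91 CPM) and Prg2 (6.77 ± 0.16, 1370 against 12.7 CPM), and Car2 was the 1 erythroid gene tested and was also higher (2.99 on the log2 scale). The pDC cultures were higher in all 3 tested B cell genes (Cd79b and Cd22 among them), both T cell genes (Cd5 and Tcf7), the 1 NK cell gene (Klrd1, which pDC also express) and all 4 stem and progenitor genes, with Cd34 at -3.68 ± 0.29. Among the sorted populations the B cell list was highest in splenic pDC (1140 CPM, 375 CPM in preDC). The T cell list was second highest there (63.4 CPM, 101 CPM in MP). Higher levels of these lists in pDC cultures thus need not come from other blood cells.

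**Figure D1:**
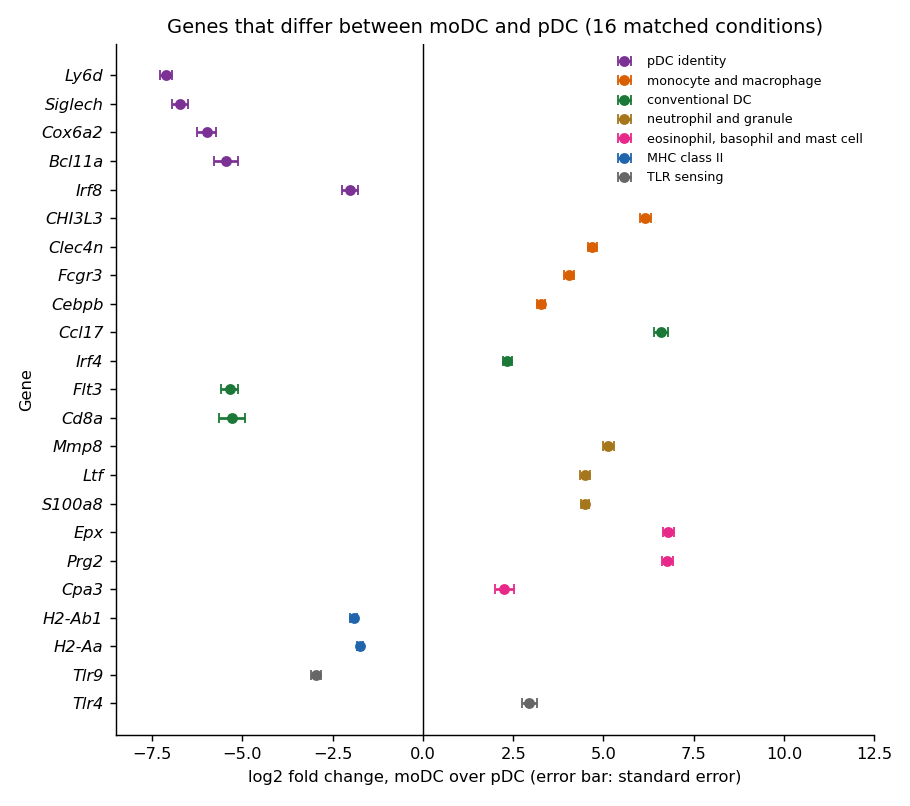
Log2 fold change of moDC over pDC (x axis, error bars are standard errors) for named genes (y axis), coloured by gene list, from 16 matched conditions. The pDC genes lie down to -7.11 (Ly6d) and the eosinophil genes up to 6.79 (Epx).

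Among the largest differences outside the lists were Ptx3, a secreted pentraxin (7.13 ± 0.20, 603 against 4.17 CPM, adjusted p = 2.19e-21 by edgeR), the lectin Mgl2 (7.09 ± 0.18), and Inhba, a subunit of activin (6.18 ± 0.34). Cd7 had 3 counts over the moDC libraries and 1023 over the pDC libraries, a ratio of 0.00291 (95% counting interval 0.000599 to 0.00853). In total 1755 of 8056 tested genes were called at an adjusted p below 0.05 and a fold of at least 2, 955 higher in moDC and 800 lower, and 1071 had the same sign in all 16 pairs. Scaling by column totals alone gave 770 higher and 1207 lower, and moved the median of all genes by -0.25. For every list above, the counts adjusted over the list alone equalled those over all genes. By camera the pDC identity, monocyte and macrophage, neutrophil, stem cell, B cell and basophil lists held their calls with an estimated correlation (adjusted p = 0.00267, 0.00267, 0.00782, 0.0147, 0.0177 and 0.00571), and the inflammatory, MHC class II, cell cycle and DC maturation lists did not. The pDC libraries had more counts spread over genes that DC are not known to use: 1108 olfactory receptor genes summed to 570 to 3810 CPM there and to 130 to 344 CPM in moDC libraries. With no filter on low counts, 1251 genes were called higher and 8457 lower.

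The next question was how each cell type responded to each ligand, with the 4 and 6 h libraries combined against the untreated library. In moDC with LPS, Rsad2, an interferon-induced antiviral enzyme, rose by 7.91 ± 1.7 on the log2 scale (6350 against 26.2 CPM), and the chemokine Cxcl10 by 7.90 ± 1.5 (2910 against 11.9 CPM). Il12b, the shared subunit of the cytokines IL-12 and IL-23, rose by 8.33 ± 1.7 (14700 against 45.2 CPM, adjusted p = 0.00363, edgeR). Nos2, the inducible nitric oxide synthase, had 260 counts over both treated libraries and 0 in the untreated one, at least 62.5-fold higher with a floor of 3 counts in the untreated library. The costimulatory receptor Cd40 rose (5.65 ± 1.3, 1800 against 35.7 CPM), as did the transcription factors Irf7 (5.45 ± 1.1) and Irf8 (1.96 ± 0.37, 604 against 155 CPM, adjusted p = 0.00249, edgeR). The monocyte chemokine receptor Ccr2 fell (-2.70 ± 0.53, 62.5 against 412 CPM), as did Tlr4 (-2.41 ± 0.46) and the replication gene Mcm7 (-2.11 ± 0.46). Cebpb had 0.97 ± 0.36 with an adjusted p of 0.0993 and was not called.

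By list, LPS raised 25 of 30 interferon-stimulated genes in moDC (29 adjusted over the list alone), 24 of 27 inflammatory genes (27 adjusted over the list alone), 8 of 15 DC maturation genes (12) and 4 of 8 IRF family genes (4), and 4 of 21 cell cycle genes fell (8). By camera with an estimated correlation, adjusted p = 0.0846 for interferon-stimulated genes, 0.0171 for inflammatory genes, 0.0846 for DC maturation and cell cycle genes, and 0.0344 for the IRF family. CpG B raised Il12b in moDC by 8.37 ± 1.7 (15000 against 45.2 CPM), Cxcl10 by 7.52 ± 1.5 and Irf8 by 1.99 ± 0.37 (616 against 155 CPM, adjusted p = 0.00434, edgeR). It raised 27 of 30 interferon-stimulated genes (29 adjusted over the list alone; camera adjusted p = 0.113 with an estimated correlation) and 20 of 27 inflammatory genes (25; 0.0324), and the inhibitory ligand Cd274 (2.93 ± 0.55, 1000 against 131 CPM).

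PAM raised 8 of 27 inflammatory genes in moDC (21 adjusted over the list alone; camera adjusted p = 0.0226 with an estimated correlation), and of 30 interferon-stimulated genes edgeR called 0 either way (0 adjusted over the list alone). The cytokine Il1b rose by 5.06 ± 0.89 (8980 against 269 CPM, adjusted p = 0.00593, edgeR), and the LPS co-receptor Cd14 by 2.64 ± 0.52. The collagenase Mmp13 had 306 counts over both treated libraries and 1 in the untreated one, a ratio of 137 (95% counting interval 24.3 to 5410), and the neutrophil growth factor Csf3 was at least 21-fold higher. Irf8 had 0.62 ± 0.35 and was not called. With CpG A no gene was called in moDC by edgeR, at 577 genes with an unadjusted p below 0.05, and DESeq2 called 1. Cxcl10 had a log2 fold change of 5.09 ± 1.4 (413 against 11.9 CPM, adjusted p = 0.382, edgeR) and Irf1 one of 2.92 ± 0.60 (254 against 33.3 CPM, adjusted p = 0.194). Adjusted over the list alone, 13 of 30 interferon-stimulated genes (camera adjusted p = 0.239 with an estimated correlation) and 2 of 27 inflammatory genes were higher with CpG A.

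Over all genes, edgeR called 623 of 8056 in moDC with LPS (432 higher, 191 lower), 77 with PAM (53 and 24), 0 with CpG A and 514 with CpG B (371 and 143). Scaling by column totals turned the balance, to 312 higher and 673 lower with LPS, 51 and 55 with PAM and 275 and 343 with CpG B, and moved the median of all genes by -0.44, -0.23 and -0.31. With PAM, DESeq2 gave 61 higher and 13 lower. The counts also rested on both late libraries: without the 6 h library they were 281 (LPS), 13 (PAM) and 170 (CpG B), and without the 4 h library 384, 31 and 219. The 1 and 2 h libraries in place of the late ones gave 31 (LPS), 6 (PAM) and 32 (CpG B).

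The libraries called pDC are of Flt3L cultures that also held conventional DC genes, such as Clec9a (100 CPM with CpG A and 36.6 CPM with CpG B). Which cells of these cultures responded to a ligand was not tested. In pDC with LPS, Oasl1, an interferon-induced antiviral protein, rose by 7.5 ± 1.5 (1580 against 8.42 CPM), Cxcl10 by 7.17 ± 1.5, Cd40 by 6.27 ± 1.3 (2630 against 33.7 CPM) and the T cell attracting chemokine Ccl22 by 5.36 ± 0.93 (11500 against 280 CPM, adjusted p = 0.000775, edgeR). The phosphatase Dusp2 rose by 4.20 ± 0.47 (adjusted p = 2.37e-05). The progenitor gene Cd34 fell (-3.44 ± 0.63, 18.9 against 211 CPM), as did Ccr2 (-2.66 ± 0.48, 113 against 716 CPM), and Cebpa, a myeloid transcription factor, went from 47 counts to 2 over both treated libraries, a ratio of 0.0276 on the CPM scale (95% counting interval 0.00325 to 0.105). Of the interferon-stimulated list 29 of 30 genes rose (30 adjusted over the list alone), of the inflammatory list 19 of 27 (19) and of the DC maturation list 13 of 15 (13). Camera gave adjusted p = 0.12, 0.0643 and 0.0643 with an estimated correlation. Irf8 had -0.55 ± 0.31 (adjusted p = 0.256) and was not called.

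PAM raised Il1b in pDC by 5.12 ± 0.92 (3150 against 90.6 CPM, adjusted p = 0.00352, edgeR), Ccl22 by 4.80 ± 0.91 and Cd40 by 5.02 ± 1.2, while Irf8 fell (-1.33 ± 0.30, 627 against 1570 CPM, adjusted p = 0.0153). Of the inflammatory list 14 of 27 genes rose (18 adjusted over the list alone; camera adjusted p = 0.0922 with an estimated correlation), and edgeR called 0 of 30 interferon-stimulated genes either way (0 adjusted over the list alone). CpG A raised interferon-stimulated genes in pDC, 24 of 30 (30 adjusted over the list alone; camera adjusted p = 0.0717 with an estimated correlation), led by Cxcl10 (7.54 ± 1.5, 2400 against 12.6 CPM) and with the cytokine Tnf at 4.41 ± 0.82 (1970 against 92.7 CPM, adjusted p = 0.00599, edgeR). It raised 10 of 27 inflammatory genes (14; 0.0717), and Irf8 had -0.18 ± 0.31.

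CpG B gave the most calls in pDC (1386 genes). Il12b rose by 8.60 ± 1.7 (9900 against 25.3 CPM, adjusted p = 0.0011, edgeR), the surface receptor Cd8a by 5.76 ± 0.76 (585 against 10.5 CPM) and Ccr7, the receptor that guides DC to lymph nodes, by 3.60 ± 0.64 (3310 against 274 CPM). The peptide loading gene H2-DMa fell (-2.15 ± 0.32, 194 against 863 CPM), as did Ccr2 (-3.52 ± 0.49), Cd34 (-3.98 ± 0.63) and Irf8 (-1.06 ± 0.30, 753 against 1570 CPM, adjusted p = 0.0166). CpG B raised 28 of 30 interferon-stimulated genes (30 adjusted over the list alone; camera adjusted p = 0.238 with an estimated correlation), 19 of 27 inflammatory genes (20; 0.11) and 11 of 15 DC maturation genes (13; 0.137). The pDC identity list went both ways, with 4 of 19 higher and 6 lower (4 and 7 adjusted over the list alone), and 4 of 12 MHC class II genes fell (4 adjusted over the list alone; 0.592).

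Over all genes, edgeR called 1112 of 8056 in pDC with LPS (677 higher, 435 lower), 318 with PAM (146 and 172), 244 with CpG A (203 and 41) and 1386 with CpG B (653 and 733). Scaling by column totals gave 422 higher and 1078 lower with LPS, 159 and 75 with CpG A and 463 and 1089 with CpG B, with the median of all genes moved by -0.47, -0.28 and -0.32, and by -0.1 with PAM. DESeq2 gave 158 higher and 95 lower with PAM and 227 and 14 with CpG A. Without the 4 h library the counts were 657 (LPS) and 179 (PAM), and without the 6 h library 41 (PAM) and 17 (CpG A). The 1 and 2 h libraries gave 7 (LPS), 21 (PAM), 0 (CpG A, whose early arm is the 1 h library) and 95 (CpG B).

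**Figure D2:**
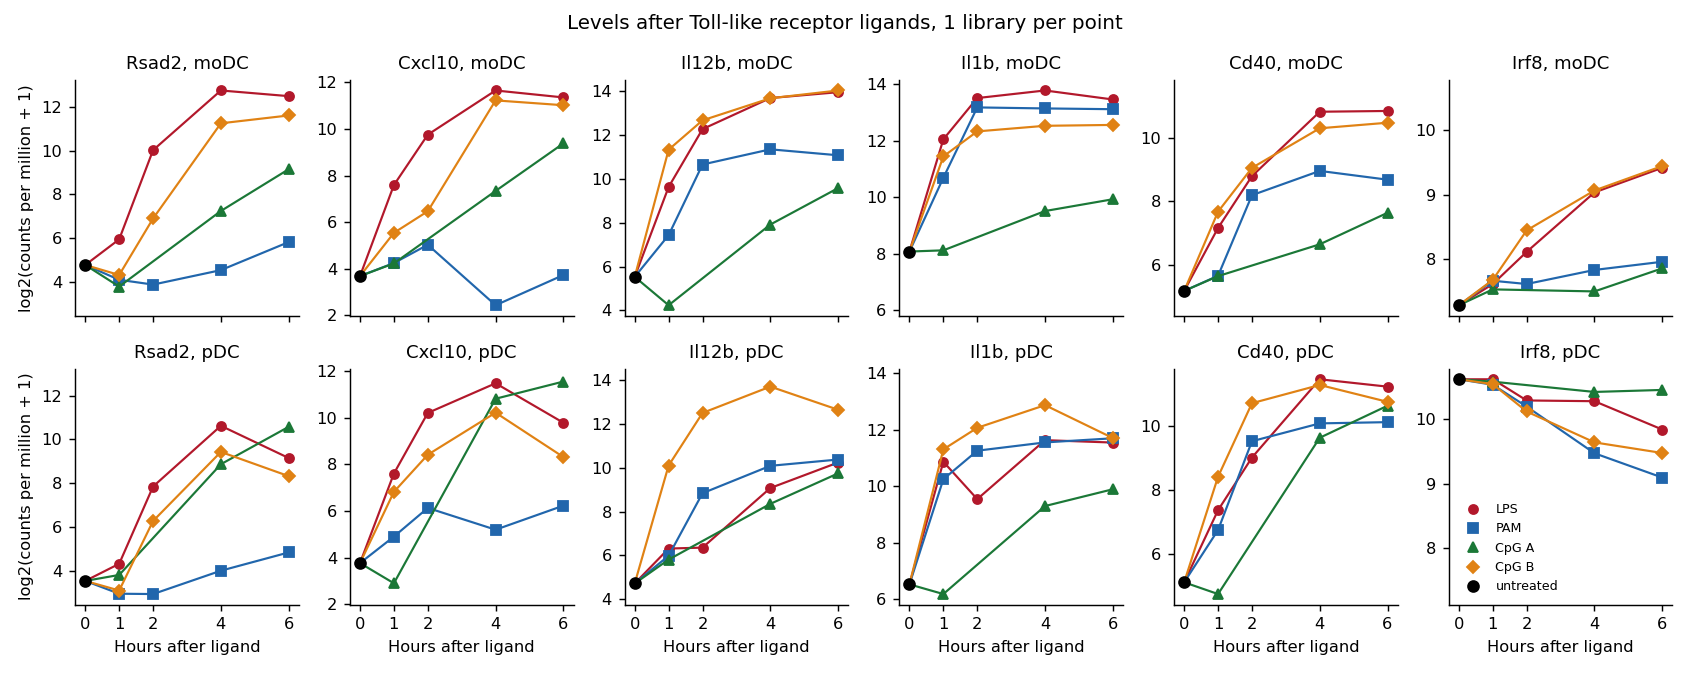
Levels of 6 genes as log2(CPM + 1) (y axis) by hours after the ligand (x axis, 0 is the untreated library) in moDC (top) and pDC (bottom), 1 library per point and no error bars. Irf8 ends above the untreated level with LPS and CpG B in moDC (604 and 616 against 155 CPM, means of 4 and 6 h) and below it with PAM and CpG B in pDC (627 and 753 against 1570 CPM).

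Comparing the 4 and 6 h libraries with the 1 h library of the same ligand asks how the responses changed with time. Interferon-stimulated genes rose late for 29 of 30 in moDC (camera adjusted p = 0.198 with an estimated correlation) and 30 of 30 in pDC (0.367). Of the immediate early genes, which peak within the first hour, 7 of 17 fell in moDC (0.198) and 10 of 19 in pDC (0.723). In moDC Rsad2 rose by 5.83 ± 0.63 (2180 against 24.9 CPM), Il12b by 3.63 ± 0.34 (7460 against 828 CPM) and Cd40 by 2.77 ± 0.27, while the early transcription factor Egr1 fell (-3.54 ± 0.41, 10.5 against 180 CPM). In pDC Isg15, a ubiquitin-like antiviral protein, rose by 5.14 ± 0.52 (3360 against 73.4 CPM, adjusted p = 4.89e-06, edgeR) and Ccl22 by 3.55 ± 0.23 (7790 against 620 CPM), and Egr1 fell (-5.38 ± 0.47, 11.5 against 541 CPM), as did Cebpa (-2.74 ± 0.30) and H2-DMa (-1.37 ± 0.21). Irf8 had 0.83 ± 0.23 in moDC (380 against 181 CPM, adjusted p = 0.021) and -0.78 ± 0.17 in pDC (1020 against 1660 CPM, adjusted p = 0.00281), both under the fold of 2 needed for a call.

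Of the inflammatory genes 13 of 25 rose late in moDC (camera adjusted p = 0.198 with an estimated correlation) and 11 of 24 in pDC (0.367). Of the cell cycle genes 2 of 20 fell in moDC (0.198) and 4 of 20 in pDC (0.452). The counts of these 4 lists were equal when adjusted over the list alone. Over all genes 459 of 6426 were called in moDC (356 higher, 103 lower) and 1316 of 7009 in pDC (666 and 650). Column totals gave 266 and 201 in moDC and 530 and 953 in pDC, with shifts of -0.17 and -0.19. The moDC count was 188 without LPS, 249 without CpG B and 192 without the 6 h libraries.

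Whether the late change differed between the cell types was tested as an interaction over the 4 ligands. Irf8 did differ, by 1.59 ± 0.30 (0.877 in moDC and -0.734 in pDC, adjusted p = 0.00343, edgeR), with the same sign for all 4 ligands. Tlr3, the receptor for double-stranded RNA, differed by 4.63 ± 0.75 (1.26 and -1.82) and Cebpa by 3.0 ± 0.55 (0.00739 and -2.16). For both genes the mean changes in brackets lie nearer to each other than the fitted difference. Tlr3 was near the floor in moDC with CpG A, with 12 counts over both late libraries (10 CPM) and 0 in the untreated one. Socs2, a suppressor of cytokine signalling, went the other way (-2.68 ± 0.35, 0.0419 and 2.3, adjusted p = 8.79e-05), as did Ccl22 (-1.90 ± 0.34) and Ccr7 (-1.60 ± 0.37). Of the DC maturation list 4 of 15 genes rose less in moDC (4 adjusted over the list alone; camera adjusted p = 0.654 with an estimated correlation), and of 30 interferon-stimulated genes 1 did (0 adjusted over the list alone). In total 284 of 7781 genes were called, 159 with a more positive change in moDC and 125 with a more negative one. The count was 32 without the 6 h libraries, 85 without 4 h, 93 without PAM, 97 without CpG B, 109 without LPS and 224 without CpG A.

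LPS and PAM were compared within each cell type over the 4 times. In moDC every called gene was higher with LPS: Rsad2 by 6.66 ± 0.60 (3010 against 23.4 CPM), the interferon-inducible Ifi205 by 4.83 ± 0.36 (102 against 3.24 CPM, adjusted p = 0.000109, edgeR) and Il12b by 2.27 ± 0.19 (7660 against 1430 CPM). Of the interferon-stimulated list 8 of 17 tested genes were higher (17 adjusted over the list alone; camera adjusted p = 0.315 with an estimated correlation), and of the inflammatory list 6 of 24 (8; 0.177). In pDC Oasl1 was higher by 5.21 ± 0.41 (921 against 20.3 CPM) and Cxcl10 by 4.18 ± 0.45 (1400 against 57.4 CPM, adjusted p = 0.00154, edgeR), with 18 of 23 interferon-stimulated genes (23 adjusted over the list alone; 0.362) and 0 of 21 inflammatory genes (3; 0.665). In all, 64 of 5676 genes were called in moDC and 34 of 6404 in pDC, none of them lower by edgeR. Il12b was the only gene whose LPS to PAM difference was called as differing between cell types (3.12 ± 0.44 larger in moDC, adjusted p = 0.0213, edgeR, 1 of 7289 genes), at 346 genes with an unadjusted p below 0.05. The block for time carried these counts: without it they were 7 in moDC, 0 in pDC and 0 for the interaction. They also moved with single times, to 230 and 119 without 1 h, 27 in moDC without 2 h (17 in pDC), 25 and 9 without 4 h and 23 and 5 without 6 h, and the interaction had 0 calls without 4 h or without 6 h.

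CpG A and CpG B were compared at 1, 4 and 6 h. In moDC 18 of 21 inflammatory genes were lower with CpG A than with CpG B (20 adjusted over the list alone; camera adjusted p = 0.292 with an estimated correlation): Il12b by -5.60 ± 0.43 (326 against 10300 CPM), Il1b by -2.99 ± 0.20 (630 against 4680 CPM, adjusted p = 0.00013, edgeR), Tnf by -2.90 ± 0.44 (919 against 6920 CPM) and Cd40 by -2.87 ± 0.27. Of the interferon-stimulated list 9 of 25 were lower (20 adjusted over the list alone; camera adjusted p = 0.5 with an estimated correlation). Of the 125 called genes out of 5564, 119 were lower and 6 higher, the latter led by Rpph1, the RNA of ribonuclease P (2.61 ± 0.29, 278 against 45.1 CPM). The moDC CpG A libraries were among the deepest (518061 to 748152 counts). In pDC edgeR called 0 of 5642 genes, with 570 at an unadjusted p below 0.05, and DESeq2 called 31. Il12b there had -4.18 ± 0.52 (434 against 7310 CPM, adjusted p = 0.0843), and 11 of 16 inflammatory genes were lower when adjusted over the list alone (camera adjusted p = 0.963 with an estimated correlation). The difference between cell types had 0 calls of 6876 genes by edgeR, at 469 with an unadjusted p below 0.05, and 3 by DESeq2. Without the 1 h libraries the counts were 376 in moDC, 257 in pDC and 17 for the difference. In moDC the count was 27 without 4 h and 2 without the block for time, and in pDC it was 2 without 6 h.

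The perturbation experiment asked what Cebpb and Irf8 do in these cells, with 1 library per arm and so no replicate check and no test. Intervals below are 95% counting intervals. The targeted genes came first. Cebpb was at 560 CPM in moDC with the control hairpin and at 58.5 CPM with the hairpin against it, a ratio of 0.104 (0.0201 to 0.346, from 23 and 3 counts). Irf8 was at 811 CPM in pDC with the control hairpin and at 361 CPM with the hairpin against it, a ratio of 0.444 (0.25 to 0.779). Cebpb was at 453 CPM in the pDC overexpression control and at 447 CPM in the library labelled OE-Cebpb, a ratio of 0.985 (0.595 to 1.56), so the label's rise was not seen. A 3′ tag outside the transgene would not count it, and the labels do not describe the construct, so this value checks nothing. Irf8 was at 312 and 203 CPM in those libraries, and Cebpb at 203 and 300 CPM in the pDC hairpin control and the Irf8 hairpin library.

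With the hairpin against Cebpb in moDC, most measured genes of the moDC list were lower, and so were neutrophil granule and conventional DC genes. The monocyte and macrophage list had a summed ratio of 0.965 (0.904 to 1.03, 16 of 25 lower). Its median log2 ratio was -0.29, at percentile 6.37 of the random lists. Summed over the 100 genes with the largest moDC over pDC fold, the ratio was 0.639 (0.602 to 0.679), with 68 of 85 measured genes lower and a median log2 ratio of -1.11, at percentile 0 of 10000 random lists matched on expression. That list holds granulocyte genes: the ratio was 0.846 (0.787 to 0.91) for the 91 genes outside the granulocyte lists. It was 1.2 (1.1 to 1.32) for the 67 genes outside a wider set of granulocyte genes, chosen after the values were seen. These are ratios of summed counts, which a few abundant genes can carry. How many of the 91 or 67 genes were lower was not counted, so a fall limited to granulocyte genes is not shown. Chi3l3 was at a ratio of 0.162 (0.0865 to 0.285) and Ccl17 at 0.165 (0.0617 to 0.378). Neutrophil granule genes had a summed ratio of 0.373 (0.334 to 0.415) with 12 of 13 lower, among them S100a8 at 0.272 (0.222 to 0.333). The basophil, mast cell and eosinophil list had 0.256 (0.0999 to 0.586, both measured genes lower). All 8 measured conventional DC genes were lower (0.634, 0.518 to 0.775). Of the 100 pDC genes 82 are in the perturbation table, and 15 were measured in this comparison. The 82 genes had a summed ratio of 0.827 (0.572 to 1.2), and Irf8 had a ratio of 1.1 (0.403 to 3.15). MHC class II genes had a median of -1.56 (10 of 11 lower) but a summed ratio of 1.11 (0.979 to 1.27), and inflammatory genes a median of -0.16 but a summed ratio of 1.4 (1.2 to 1.65).

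With the hairpin against Irf8 in pDC, moDC genes were higher and pDC genes lower than in the hairpin control, but not than in the other pDC control. The 100 moDC genes had a summed ratio of 3.53 (3.17 to 3.94) with 58 of 73 measured genes higher, and the 82 pDC genes one of 0.311 (0.265 to 0.363) with 45 of 53 measured genes lower, at percentiles 100 and 0. The latter list, taken from whole cultures, holds stromal genes. Of these Sparc, Col1a1 and Col1a2, chosen after their values were seen, were at 963, 152 and 304 CPM in the hairpin control. With the Irf8 hairpin they were at 240, 45.1 and 150 CPM. The pDC identity list, which holds none of them, had a summed ratio of 0.409 (0.323 to 0.518, 13 of 15 lower). Siglech was at 0.212 (0.0597 to 0.622), Clec4n at 4.92 (2.76 to 9.54) and H2-Ab1 at 3.64 (2.06 to 6.94). Neutrophil granule genes were higher too (5.66, 4.65 to 6.95), and interferon-stimulated genes lower (0.452, 0.345 to 0.591, 23 of 25 lower). Outside the granulocyte lists the moDC genes had a ratio of 2.64 (2.33 to 3), and outside the wider set 2.09 (1.82 to 2.41). The other pDC control did not stand where the hairpin control did: the 100 moDC genes summed to 9940 CPM in the hairpin control, 35100 CPM with the Irf8 hairpin and 40500 CPM in the overexpression control, and the 82 pDC genes to 12100, 3760 and 2790 CPM. Against the overexpression control, taken after the values were seen, Irf8 had a ratio of 1.15 (0.7 to 1.84) in the Irf8 hairpin library and the 100 moDC genes one of 0.866 (0.828 to 0.906). Against the same control the ratio was 1.35 (1.16 to 1.55) for the 82 pDC genes, 0.832 (0.679 to 1.01) for the pDC identity genes, 0.93 (0.869 to 0.995) for neutrophil granule genes and 0.539 (0.433 to 0.665) for interferon-stimulated genes.

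In the library labelled OE-Cebpb, neutrophil granule genes were higher than in its control (1.7, 1.6 to 1.81, 10 of 11 higher), with Ltf at 2.93 (1.78 to 4.73) and Camp at 2.54 (1.59 to 3.98). The pDC identity genes were lower (0.622, 0.476 to 0.8, 9 of 10 lower), Tcf4, a factor that maintains pDC, among them at 0.381 (0.12 to 0.931), and interferon-stimulated genes were lower (0.721, 0.578 to 0.89, 23 of 27). The monocyte and macrophage genes were lower (0.857, 0.798 to 0.919, 18 of 24). The 100 moDC genes summed to a ratio of 1.16 (1.11 to 1.21) while their median was -0.16. Outside the granulocyte lists the ratio was 0.81 (0.756 to 0.867), and outside the wider set 0.6 (0.544 to 0.661). The 82 pDC genes summed to 1.1 (0.915 to 1.31) with a median of 0.80 over the 33 measured, in a library where 1 count is worth 20.3 CPM. Against the pDC hairpin control, taken after the values were seen, the 100 moDC genes had a ratio of 4.73 (4.25 to 5.27), and the 82 pDC genes one of 0.254 (0.21 to 0.305). There the neutrophil granule genes had 10.4 (8.54 to 12.7), the pDC identity genes 0.306 (0.228 to 0.407) and interferon-stimulated genes 0.605 (0.461 to 0.792). The monocyte and macrophage genes turned to higher against that control (1.23, 1.1 to 1.36).

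**Figure D3:**
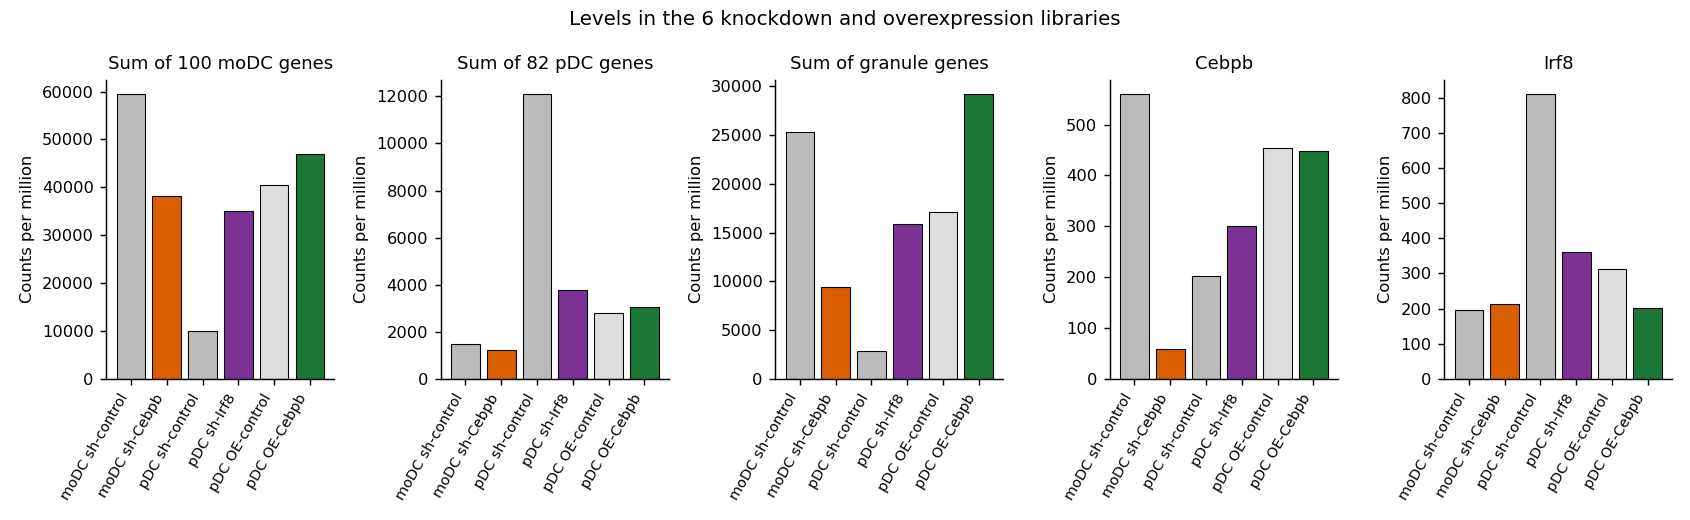
Summed CPM of 3 gene lists and CPM of Cebpb and Irf8 (y axes, from 0) in the 6 perturbation libraries (x axis), 1 library per bar and no error bars. The pDC hairpin control holds 9940 CPM of the 100 moDC genes, the Irf8 hairpin library 35100 CPM and the overexpression control 40500 CPM.

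The sorted populations show where these genes are used in mice, with 1 library per population and no test. Cebpb was highest in monocytes, at 1300 CPM in Ly6c- and 588 CPM in Ly6c+ monocytes, and between 20.3 and 60.5 CPM in the other populations. Irf8 was highest in pDC (3520 CPM), preDC (3380 CPM) and the DC progenitor CDP (2150 CPM), and lowest in Ly6c- monocytes (200 CPM). Monocyte and macrophage genes summed to 39500 CPM in Ly6c+ and 24800 CPM in Ly6c- monocytes. Conventional DC genes summed to 8110 CPM in CD8+ DC, 3810 CPM in DN DC and 3630 CPM in pDC. MHC class II genes summed to 71500 CPM in DN DC, 68900 CPM in CD8+ DC and 25900 CPM in pDC. Stem and progenitor genes led in MP (3710 CPM) and MDP (2770 CPM), and cell cycle genes in CDP (8140 CPM). The pDC identity genes summed to 29300 CPM in splenic pDC and to 19300 CPM in bone marrow preDC, where Siglech was at 1230 CPM (2660 in pDC) and Ly6d at 1180 CPM (1900 in pDC), but the chemokine receptor Ccr9 at 219 CPM (1650 in pDC) and H2-Aa at 211 CPM (7420 in pDC). Genes ahead in a single population included the Fc receptor Fcgr4 in Ly6c- monocytes (2250 CPM), Chi3l3 in Ly6c+ monocytes (2290 CPM), the lectin Cd207 in CD8+ DC (192 CPM) and the granule protease Ctsg in MDP (1960 CPM).

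**Figure D4:**
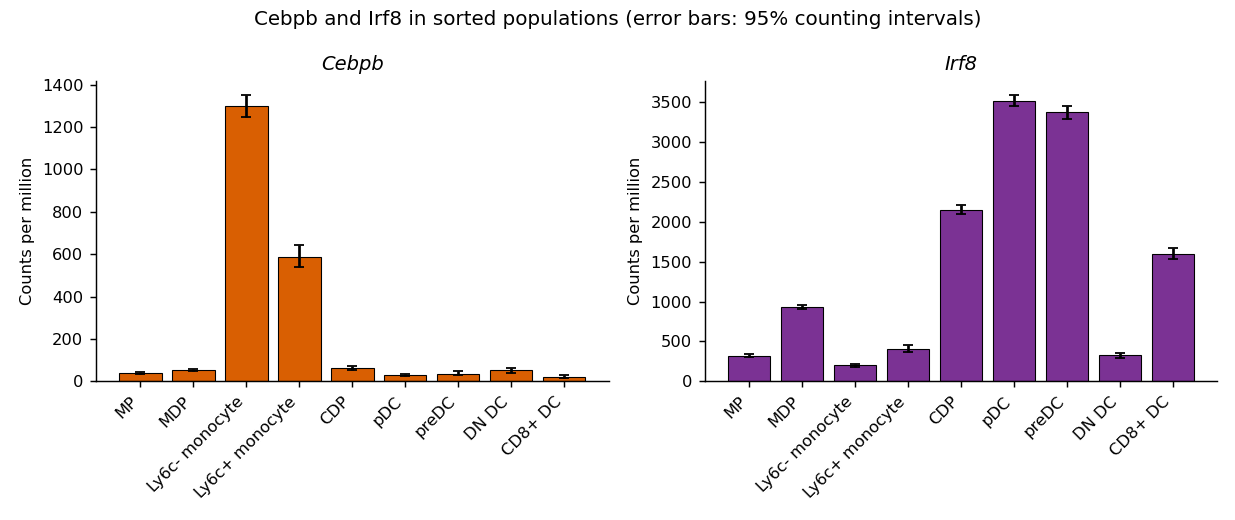
CPM of Cebpb and Irf8 (y axes, from 0) in 9 sorted populations (x axis), 1 library each, with 95% counting intervals as error bars. Cebpb is highest in Ly6c- monocytes (1300 CPM) and Irf8 in pDC (3520 CPM).

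Whether Cebpb and Irf8 run opposite to each other was asked across libraries, as 3 relations. Across the 9 sorted populations Pearson's r was -0.64 (exact permutation test, two-sided p = 0.056, adjusted 0.168) and Spearman's rho -0.567 (exact p = 0.121, adjusted 0.363). Without the 2 monocyte populations, the farthest from the median of Cebpb, r was -0.33 (exact p = 0.456), so the relation rests on the monocytes. Within the 16 moDC libraries r was 0.0715 (permutation test, two-sided p = 0.792, adjusted 0.792) and rho 0.112 (permutation p = 0.68, adjusted 0.68), with r = 0.12 when the untreated and the PAM 2 h library were left out, and r = -0.0713 without the untreated library alone. Within the 16 pDC libraries r was -0.133 (permutation test, two-sided p = 0.618, adjusted 0.792) and rho -0.159 (permutation p = 0.555, adjusted 0.68), with r = -0.306 without CpG A at 1 h and CpG B at 4 h, the farthest from the median. Without the untreated pDC library r was -0.0412 and rho -0.0357. With median ratio scaling r was 0.372 (permutation p = 0.154) and rho 0.468 (permutation p = 0.0701) in moDC, and -0.273 (permutation p = 0.306) and -0.309 (permutation p = 0.242) in pDC. Across the sorted populations this scaling gave r = -0.594 (exact permutation p = 0.0936) and rho = -0.65 (exact permutation p = 0.0666). No relation passed its adjusted threshold.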

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

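The comparisons of splits within times or ligands were chosen after the results were seen, and the other tests in this part were not. The late change from 1 h to 4 and 6 h differed between moDC and pDC for 284 genes by the interaction test. Among the named ones the difference (moDC minus pDC, log2) was 1.59 for Irf8, 4.63 for Tlr3, 3.0 for Cebpa, -2.68 for Socs2, -1.90 for Ccl22 and -1.60 for Ccr7. Of these Tlr3 was near the floor in moDC with CpG A. Over all 35 splits of the 8 combinations of cell type and ligand, 1, the real one, gave as many genes, and the highest other split gave 60. These splits ignore that both cell types share the ligands, so they do not exclude chance for the count. The splits with each ligand once on either side are 8, too few for a share under 0.05, and the highest other of them gave 0 genes. The count was 32 genes without the 6 h libraries, 85 without 4 h, 93 without PAM, 97 without CpG B, 109 without LPS and 224 without CpG A.

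The difference between LPS and PAM differed between the cell types for 1 gene, Il12b, by 3.12 on the log2 scale. Chance cannot be excluded for this count, since 3 of the 35 splits of the 8 combinations of cell type and time gave as many genes or more, up to 308. The split with 308 genes sets the 1 and 2 h values of both cell types against the 4 and 6 h values, which points to a structure of the samples by time. The splits with each time once on either side are 8, too few for a share under 0.05, and the highest other of them gave 0 genes. Without the 4 h or the 6 h libraries 0 genes were called.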

How the results depend on the processing

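Scaling by column totals alone, the fits without CpG A libraries, the other pDC control and the moDC list without granulocyte genes were chosen after the results were seen. For counts of called genes and for single values of comparisons, 143 alternatives other than leaving out 1 pair, library, ligand or time in turn were run: 101 left the result on its side, 40 moved it by more than 1.5 times or past its interval, and 2 reversed it. Named genes and lists were tallied apart, with 4555 results. Of these 4050 stayed the same, 46 became weaker, 7 became stronger, 448 moved and 4 reversed. Where no construction is named below, the cause was not tested.

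With no filter the cell type comparison called 9708 genes, PAM 230 in moDC and 522 in pDC, CpG A 82 in moDC and 434 in pDC, LPS against PAM 308 in moDC and 297 in pDC, CpG A against CpG B 357 in moDC and 223 in pDC, and the differences of these contrasts between cell types 8 and 61. A filter of 100 CPM, which tests fewer genes, gave 717 for cell type, 854 for CpG B in pDC, 201 and 509 for time in moDC and pDC, 172 for the late interaction, 18 and 0 for LPS against PAM in moDC and pDC, 41 for CpG A against CpG B in moDC and 0 for the difference of LPS and PAM between cell types. The 1 and 2 h libraries in place of the late ones, which are other samples, gave 31 (LPS), 6 (PAM) and 32 (CpG B) in moDC and 7, 21, 0 (CpG A) and 95 in pDC. Cxcl10 in pDC with CpG A reversed to -0.93 there, from the 1 h library alone.

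DESeq2 called 1 gene for CpG A in moDC, 65 for LPS against PAM in pDC, 31 for CpG A against CpG B in pDC and 3 for the difference between cell types. Without the block for time, LPS against PAM had 7 genes in moDC and 0 in pDC, CpG A against CpG B in moDC 2, and the difference of LPS and PAM between cell types 0. Column totals gave 985 genes for LPS in moDC, 57 for CpG A against CpG B in moDC (which moved the median of all genes by 0.22), and 75 and 10 for LPS against PAM and CpG A against CpG B in pDC. With the other pDC control, the log2 ratio of Irf8 in the Irf8 hairpin library reversed from -1.15 to 0.20, and that of Cebpb in the library labelled OE-Cebpb moved from -0.02 to 1.1. The correlation of Cebpb and Irf8 in moDC reversed to -0.0713 without the untreated library. The summed ratio of moDC genes reversed without granulocyte genes, with the Cebpb hairpin from 0.639 to 1.2 without the wider set, and in the library labelled OE-Cebpb from 1.16 to 0.81 without the granulocyte lists and 0.6 without the wider set. Other added values, scalings and minimum levels left the 3 targeted genes within their intervals.

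Leaving out 1 pair, library, ligand or time in turn gave 1711 to 1781 genes for cell type. Against untreated it gave 281 to 384 (LPS), 13 to 31 (PAM), 0 to 0 (CpG A) and 170 to 219 (CpG B) in moDC, and 657 to 796, 41 to 179, 17 to 334 and 960 to 1031 in pDC. For time it gave 188 to 604 in moDC and 973 to 1284 in pDC, and for the late interaction 32 to 224. LPS against PAM ranged from 23 to 230 in moDC and 5 to 119 in pDC, CpG A against CpG B from 27 to 376 and 0 to 257, and the differences between cell types from 0 to 1 and 0 to 17. Without the CpG A libraries the cell type count was 1767.

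Of the named genes, 34 of 45 lost their call with the 1 and 2 h libraries, 9 of 50 without the block and 3 of 88 with the filter of 100 CPM. Gains were 3 of 115 with no filter, 2 of 115 with column totals and 2 of 113 with DESeq2, and no named gene lost its call with DESeq2, its size factors, column totals or without CpG A libraries. Depth limits the low genes: at 1.34 to 3.92 CPM per count in the stimulation libraries and up to 25.4 CPM in the perturbation libraries, a level under 4.01 to 11.8 CPM cannot be told from 0 in the former. The fits are blocked by condition, ligand or time, except those against the untreated library, which have no block. No fit with a block for replicate number could be made, since the labels give no replicate numbers shared between groups.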

Other observations

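The tests of the Irf8 hairpin library, both forms of the test of the preDC library and the comparison of splits within times were chosen after the results were seen, except for the first form of the granulocyte test, and the others were not. Cebpe, a C/EBP factor of granulocyte maturation, was 4.36 ± 0.24 (log2, moDC over pDC) higher in moDC, at 70.8 against 3.24 CPM. In pDC the growth factor receptor Kdr rose from 1 h to 4 and 6 h by 4.91 ± 0.45 (215 against 7.13 CPM) and the acute phase gene Saa3 by 5.66 ± 0.71 (336 against 6.83 CPM), while the prostaglandin-degrading enzyme Hpgd fell (-3.61 ± 0.41). With the hairpin against Cebpb, the related Cebpa had a ratio of 3.52 (95% counting interval 1.3 to 11.9), the stress factor Atf3 one of 4 (1.51 to 13.4) and the macrophage gene Ms4a7 one of 4.8 (1.4 to 25.5), and Mgl2 had 0 counts against 20, at least 8.33-fold lower with a floor of 3 counts in the library at 0.

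Among the sorted populations, splenic pDC led in Klk1 (2690 CPM, a gene with close relatives that could share reads) and Cd8b1 (1150 CPM), DN DC in the fatty acid receptor Ffar2 (857 CPM), CDP in the proliferation gene Mki67 (948 CPM), MP in the lipid transporter Spns2 (323 CPM) and preDC in the collagen gene Col23a1 (172 CPM). Neutrophil granule genes were highest by summed level in MDP (7490 CPM) and MP (5510 CPM, 2000 CPM in Ly6c+ monocytes), but by mean log2 level in Ly6c+ monocytes (7.3, with 7.11 in MP and 6.83 in MDP).

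The first pattern weighed is the higher level of moDC genes in the Irf8 hairpin library than in the pDC hairpin control, a ratio of 3.53. A hairpin control that stands apart is a candidate explanation, with a ratio of 0.866 (0.828 to 0.906) against the other pDC control, and Sparc, a stromal gene chosen after its values were seen, at 963 CPM in the hairpin control, 240 CPM with the Irf8 hairpin and 7.62 CPM in the other control. The other control may as well be the library out of place, since it lay nearer to the moDC hairpin control in moDC genes (40500 and 59500 CPM, 9940 CPM in the pDC hairpin control), in pDC genes (2790 and 1480 CPM, 12100 CPM) and in Irf8 (312 and 195 CPM, 811 CPM), so which of the controls stands apart stays open. Granulocytes in the Irf8 hairpin library stay open too: without the 9 genes of the granulocyte lists the ratio of the other 91 genes was 2.64 (2.33 to 3), but these still hold granulocyte genes, and without a further 24 it was 2.09 (1.82 to 2.41), with an interval that reaches below the ratio of 2 set as the bound against them. An effect of the Irf8 knockdown itself was not tested and stays open, as each arm is 1 library.

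The second pattern is the level of pDC genes in the preDC library, 19300 CPM against 29300 CPM in the pDC library for the 20 genes of the identity list. Splenic pDC mixed into the preDC library would give genes specific to pDC 1 ratio between both libraries, but 13 of 37 such genes (35.1%) lay more than 2 times from the median ratio of 0.289, intervals included, which argues against it as the whole cause. The preDC sort also took cells without CD45RA, which pDC carry. A first form of this test, on the quartiles of the ratio (0.111 and 0.489), had left it undecided. Use of these genes by bone marrow preDC stays open. Bone marrow pDC mixed into the preDC library stay open too, since they were not analysed here and the test covers splenic pDC alone.

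The third pattern is the larger number of counts spread over silent genes in the pDC libraries, with 0.591 counts per olfactory receptor gene and library against 0.0931 in moDC. The 800 genes called lower in moDC had passed the count filter, with a median pDC count 30.4 times the olfactory mean. Taking off the mean background of each library could thus change few of them, and 755 (94.4%) were still called. This argues only against an even background of this size as their cause. A background that is uneven between genes was not tested. Of the genes called lower with no filter, 6840 fail the filter and are not olfactory receptor genes. These had a median of 0.812 counts per pDC library, 1.37 times the olfactory mean (quartiles 1.06 and 1.9), so background may account for their calls. No biological explanation was tested.

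Other splits of the same libraries were counted for each tested comparison. For cell type 1 of the 100 splits drawn, the real one, gave as many genes (1755, highest other 977). For time in pDC it was 1 of 100 as well (1316 genes, highest other 1058), and in moDC 2 of 100 (459 genes, highest other 761). These shares lie under 0.05. However, the splits mix libraries across the conditions or ligands that the fits hold as blocks. Splits within those blocks were not run, so the shares do not exclude chance. The split with 761 genes sets the late LPS and CpG B libraries against all others. With the ligand as a block, it compares 4 and 6 h with 1 h within LPS and CpG B. It thus holds the real time difference of those ligands. For LPS against PAM the count over splits does not exclude chance either: 3 of 32 splits gave as many genes in moDC (64, highest other 403) and 3 of 32 in pDC (34, highest other 503), where the others of 35 splits follow time and could not be fitted. The splits with 403 and 503 genes part LPS from PAM at 4 and 6 h and put both 1 h libraries on 1 side, so they hold the real difference of those times, and point to a structure of the samples by time. The splits with each time once on either side are 8, too few for a share under 0.05, and the highest other of them gave 3 genes in moDC and 0 in pDC. For CpG A against CpG B there are 10 splits in each case, too few for a share under 0.05, with 125 genes in moDC (highest other 0), 0 in pDC (highest other 0) and 0 for the difference between cell types (highest other 1), so that 1, 10 and 10 splits gave as many.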
